A study of Drosophila melanogaster with 3 samples.

How the data were processed

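Chromatin from 3 biological replicates of whole Drosophila melanogaster embryos expressing a fusion of Phol and green fluorescent protein was precipitated with an antibody against the fluorescent protein and sequenced, per the labels. The chromatin was sheared by sonication with a size range of 200 to 800, per the labels. The labels number the replicates 1, 2 and 3 and describe them as biological replicates. Whether these came from separate collections of embryos is not stated, so the SD over them measures the spread between these samples.

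The authors deposited 5 peak lists on the dm6 build. Per the readme notes deposited with the samples, a list was called on each replicate with a control alignment, a further list on the pooled replicates, and the last holds the peaks of the pooled list that passed a threshold on the irreproducible discovery rate between replicates. The control is not analysed here. The aligner, the peak caller, their versions and the threshold value are not given in the sources used here. Each replicate list and the pooled list hold 30000 peaks, and the reproducible list holds 10264. Tested on the files, the reproducible list is the strongest 10264 peaks of the pooled list. All of its peaks lie on 2L, 2R, 3L, 3R, 4 and X.

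The deposited signal value of each peak is as the authors' peak caller gave it, with no stated scale, and was used here only to rank or filter peaks within a list. It ranged from 225 to 17120 in the reproducible list. The deposited −log10 q-value of a peak sits at a shared maximum of 4.35 for all 10264 reproducible peaks, so it could not rank them and was not used further. A list of fixed length does not show how many sites a replicate held, so ranks and shares were compared, not list lengths. Pooling gives the deeper replicates more weight in the reproducible list, and read depth is unknown. For this reason many shares are given also as the mean and SD over the strongest 10264 peaks of every replicate. No peak row was identical between replicates (0 in each pair).

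Peaks were placed on the release 6 genome with the Ensembl release 115 annotation, in 1-based coordinates. No peak ran past a chromosome end, 99.9% of annotated start codons read ATG in the sequence, and 13944 gene symbols were shared with the RefSeq table, 100% of them overlapping in position. The 13945 protein-coding genes on the 6 arms were analysed. A gene was called occupied if a summit lay within 500 bp of any of its annotated starts. Summits were put in the first class that applied of promoter (within 500 bp of a start of any gene), 5′ UTR, 3′ UTR, coding exon, intron or other gene body, and intergenic.

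Peaks of different lists were counted as shared when their summits lay within 250 bp. Random placements drew positions on the same chromosome outside unsequenced bases, 1000 times for the promoter share and 100 times for overlaps and annotation classes. DNA words were searched on both strands in windows of 101 bp centred on the summit and on positions 500 bp to either side. GCCAT is the core of the site bound by Pho and Phol, and N stands for any base. Shares were compared by Fisher's exact test, two-sided, with Wald 95% intervals of the odds ratio, and Benjamini-Hochberg adjustment over the 22 words and over the 18 gene lists. Fisher's exact test treats neighbouring peaks and genes as independent, and its p-values cover counting error only. For gene bodies and for matched gene lists, 10000 random lists were drawn, and the smallest two-sided p they can give is 2.0e-04. Percentile ranks of named peaks are the rank of the strongest peak within 250 bp in each replicate list, as a percent of 30000.

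The main tests, the gene lists, the words and the genes to name were fixed before the data were examined. Chosen afterwards were the rank correlations, the tests of promoter share, GCCATNTT and the DNA replication-related element by peak strength, the orientation of GCCATNTT, orientation without start codons, the comparison of words with each other ordering of their letters, of which only the mean for GCCAT was fixed beforehand, the base composition at the summits, divergent promoters by region, and the chorion list without Cp110 and Cp190. The genes named are phol and its paralog pho, the 20 strongest peaks with the gene of the nearest start, the 3 occupied members of each list with the strongest peaks, the 8 Hox genes, en, inv and the Polycomb group members. Other genes named are unoccupied or occupied members of a short count, or were chosen after their values were seen. Symbols of the lists that did not match a protein-coding gene of the annotation are not used here (SmG, Isy1, lat, SA, calypso and nos). The scripts were tested on simulated data. For planted shares of 39.1% at promoters, 61.3% shared and 21.6% with GCCATNTT, in 10264 peaks, they returned 39.0%, 61.3% and 21.5%. For GCCATNTT at 10264 random peaks, drawn a single time with no planted excess, the odds ratio against flanks was 0.863 instead of 1. Of gene lists of the real sizes over 13945 genes, 99.7% of those planted at 80% occupied and 87.7% of those planted at 10% were called in the right direction, and 97.5% of lists at the base rate were not called.

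Alternatives covered each replicate left out, the strongest 5132 peaks, other windows, other rules for shared peaks, other words and other backgrounds. With a replicate left out, the reproducible list was replaced by the peaks found among the strongest 10264 of both others, 8930, 8652 and 9194 peaks without replicates 1, 2 and 3. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.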

Results

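Pleiohomeotic-like (Phol) is a zinc-finger DNA-binding protein of the Polycomb group, the set of chromatin regulators that keep developmental genes repressed, and a paralog of Pleiohomeotic (Pho). The binding of Phol was measured by chromatin immunoprecipitation and sequencing in embryos of Drosophila melanogaster that carried a transgene for Phol with green fluorescent protein at its C terminus, with an antibody against the green fluorescent protein. Whole embryos of mixed sex aged 0 to 16 hours were used, and the labels number 3 biological replicates, which form a single group. Each replicate has its own list of 30000 peaks. A further list of 30000 peaks comes from the pooled reads, and 10264 peaks of it form the list that passed the authors' test of reproducibility between replicates, called the reproducible list here. Read depths are not given in the peak lists, so the counting precision behind a single peak is unknown. The question addressed is where tagged Phol is found in the genome and how well the replicates repeat it.

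The replicates found largely the same places. Of the strongest 10264 peaks of each replicate, 89.8% were shared between replicates 1 and 2, 84.8% between replicates 1 and 3, and 87.2% between replicates 2 and 3, counting summits within 250 bp of each other. The mean over the 3 pairs was 87.3% ± 2.53 (SD), against 3.71% for peaks placed at random on their own chromosomes (permutation test, 100 placements, two-sided p = 0.0198, the smallest they can give). The reproducible list is the strongest 10264 of the peaks called on the pooled reads of these replicates. Of its peaks, 97.9% were in all 3 full lists and 80.1% in the strongest 10264 peaks of all 3. These shares follow in large part from the pooling and the cut by strength that made this list. Over its peaks, Spearman's rho of the peak ranks was 0.909 for replicates 1 and 2, 0.815 for replicates 1 and 3, and 0.860 for replicates 2 and 3. Peaks are not independent replicates, and these values describe the selected peaks only.

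The strongest Phol peaks lay mostly at the starts of genes, of several kinds. The highest signal value was at the start of fl(2)d, a regulator of splicing and of RNA methylation (2R, 13824029 to 13825129, release 6 coordinates). The next was at the shared promoter of cg, which encodes the Polycomb group DNA-binding protein Combgap, and mRpS16, a mitochondrial ribosomal protein (2R, 14173275 to 14174284). The 20 strongest peaks also included the starts of the insulator protein gene CTCF (3L, 7356266 to 7357108), of Jarid2, which encodes a subunit of Polycomb repressive complexes (3L, 9476583 to 9477672), of the chromatin remodelling genes osa and Chd1, of the spliceosome gene SmD3, and of RpS30 and RpL14. The other starts were those of the snoRNA host gene Uhg2, the protein phosphatase genes Pp1-87B and ssh, the RNA decay gene Smg5, the nucleosome factor gene Ndf, Nacalpha, which encodes a ribosome-associated chaperone, and CG14100, CG12099 and CG10555. Of these 20 peaks, 18 had their summit within 500 bp of an annotated start, and every one of the 20 was within the strongest 0.11% of each replicate list.

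Outside starts, 2 of the 20 strongest peaks remained. The peak of mts, the catalytic subunit of protein phosphatase 2A, had its summit 601 bp from the start, in the gene body (2L, 7827855 to 7828881). The other lay in the bithorax complex of Hox genes, 13199 bp from the start of mir-iab-8 (3R, 16869280 to 16869845). The promoter of phol itself held a peak (3L, 9455724 to 9456432, rank 1315, summit 295 bp from the start) that stood in the strongest 4.44% ± 0.577 (SD, n = 3) of the replicate lists. The promoter of pho held one (4, 1181650 to 1182081, rank 2753) at 23.7% ± 24.1 (SD, n = 3), and replicate 3 placed it lower, at 51.2%.

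Nearly equal shares of the peaks lay at promoters and elsewhere. Of 10264 summits, 5080 (49.5%, 95% Wilson interval 48.5 to 50.5) lay within 500 bp of the start of an annotated transcript, against 13.6% for random placements, a ratio of 3.65 (permutation test, 1000 placements, two-sided p = 0.00200, the smallest they can give). Random positions 5 to 20 kb from each summit, a background added afterwards, gave a higher random share, 17.8%. The observed share was 49.8% ± 2.98 (SD, n = 3) over the replicates. Coding exons were almost free of summits, with 33 summits (0.322%), 0.0246 times the random share. The share in 3′ UTRs was 0.926% against 5.08% at random, in introns and other parts of genes 32.4% against 40.3%, and between genes 16.5% against 27.2%. The observed shares in these 4 classes lay outside the range of 100 random placements. Strong peaks were at promoters more often than weak ones, with 60.1% of the strongest 2566 peaks and 41.2% of the weakest 2566 (odds ratio 2.15, Fisher's exact test, two-sided p = 1.1e-41).

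**Figure D1:**
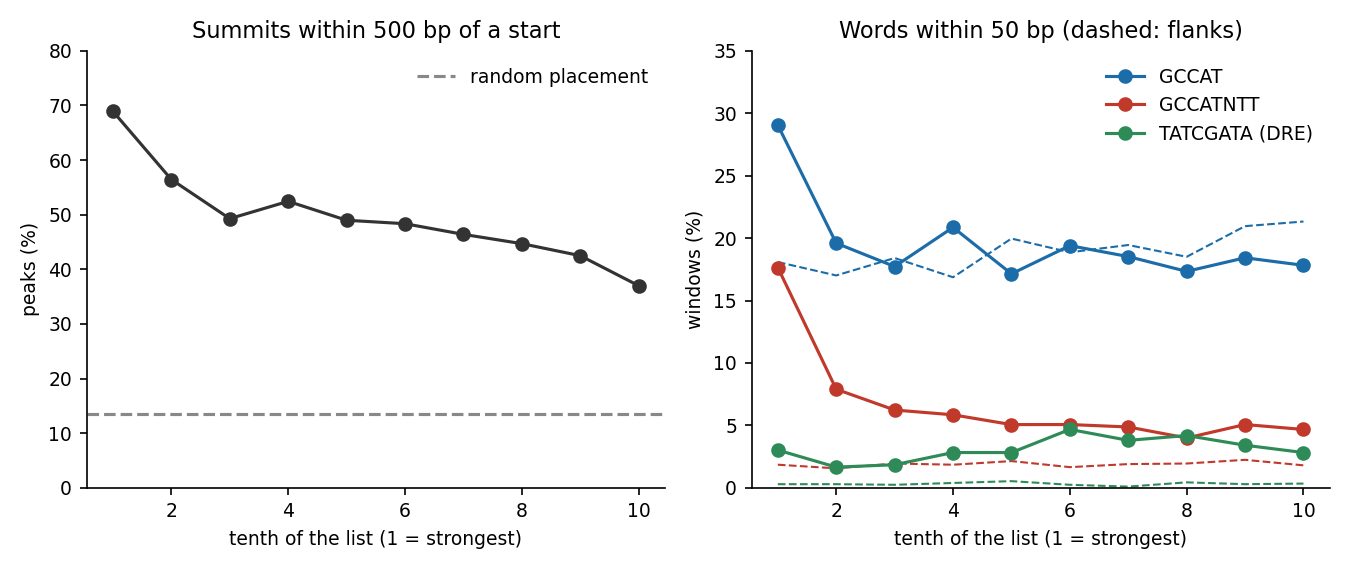
Share of the reproducible peaks, in percent, with the summit within 500 bp of a start (left) and with each DNA word within 50 bp of the summit (right), in 10 parts of the list from the strongest, at 1, to the weakest. Dashed lines are random placement (left) and windows 500 bp from the summits (right); GCCATNTT falls from 17.6% in the strongest 1026 peaks to 4.67% in the weakest.

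The extended site of Pho and Phol was the clearest Phol sequence at the summits, and it was concentrated in the strongest peaks. GCCATNTT stood within 50 bp of the summit in 681 peaks (6.63%) against 1.89% of flanking windows 500 bp away (odds ratio 3.69, 95% interval 3.25 to 4.19; Fisher's exact test, adjusted p = 3.3e-93), and in 6.44% ± 0.913 (SD, n = 3) of the strongest peaks of the replicates. It reached 17.6% in the strongest 1026 peaks, and 13 of the 20 strongest peaks held it, among them those at fl(2)d, cg, CTCF and osa. The shorter core GCCAT, fixed as the main word, did not pass the test over the whole list, with 2010 peaks (19.6%) against 18.9% of flanks (odds ratio 1.04, 95% interval 0.982 to 1.11; Fisher's exact test, two-sided p = 0.177). It did in the strongest 5132 peaks (odds ratio 1.20), within 25 bp of the summit (1.25), and at promoter peaks against promoters without a peak (1.37). Within 100 bp GCCAT was less frequent at summits than in flanks (odds ratio 0.870, Fisher's exact test, two-sided p = 7.2e-08).

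GCCAT was found in 22.9% of the strongest 2566 peaks and 17.9% of the weakest 2566 (odds ratio 1.36, 95% interval 1.19 to 1.56; Fisher's exact test, two-sided p = 9.1e-06). GCCATNTT was found in 11.3% and 4.56% of these peaks (odds ratio 2.68). The difference for GCCAT passed the test among promoter peaks (odds ratio 1.66) and not among peaks away from promoters (odds ratio 1.01, Fisher's exact test, two-sided p = 1), and the change between these groups was not tested.

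Over all summits, words of some other promoter factors had higher odds ratios than GCCATNTT, at fewer summits. The DNA replication-related element TATCGATA was at 3.11% of summits against 0.317% of flanks (odds ratio 10.1), Motif 1 (GGTCACAC, the site of M1BP) at 2.03% against 0.180% (odds ratio 11.5), and the core promoter word Ohler motif 6 at 0.663% (odds ratio 5.70). Ohler motif 7 was at 5.98% with a lower odds ratio (1.97). Split by peak location, a comparison added afterwards, the DNA replication-related element had an odds ratio against flanks of 15.2 at promoter peaks. Away from promoters it had 1.57 (Wald interval 0.845 to 2.91), Ohler motif 6 had 1 and Ohler motif 7 had 0.640. Motif 1 still had 2.78 there (Wald interval 1.36 to 5.67). These words were not compared with promoters without a peak, so an excess from promoter location alone is not excluded. The site of the insulator protein Su(Hw), TGCATACTTT, was at 28 summits (odds ratio 3.51). The GAGA factor word GAGAGAG was less frequent at summits (1.14% against 2.28%), as were the GT repeat bound by Combgap (1.24% against 3.43%), the site of Spps and related factors (3.58% against 7.31%) and the site of the early activator Zelda (0.360% against 0.619%). Of the 22 words fixed beforehand, 10 were more frequent at summits, 7 less frequent and 5 neither (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). The summits were poor in G and C, with 33.5% against 44.2% in windows 500 bp away, and the control word GAAAGCTT, which has no named factor, was also more frequent (odds ratio 1.65). Of 100 other orderings of the letters of each word compared this way, a comparison added after the data were seen, 0 reached the odds ratio of GCCATNTT, TATCGATA or GGTCACAC, and 26 reached that of the control word. The median odds ratio of these orderings was 0.961, 1.83, 0.490 and 1.22 in turn, so base composition alone can lower or raise a word. The less frequent words, the Ohler motifs and the Su(Hw) site were not compared with other orderings, and their differences may come from base composition.

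Over all peaks, the DNA replication-related element had no steady trend with peak strength. It was found in 2.14% of the strongest 2566 peaks and 3.43% of the weakest 2566 (odds ratio 0.617, 95% interval 0.438 to 0.868; Fisher's exact test, two-sided p = 0.00645), but in 3.02% of the strongest 1026 and 2.82% of the weakest 1027.

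**Figure D2:**
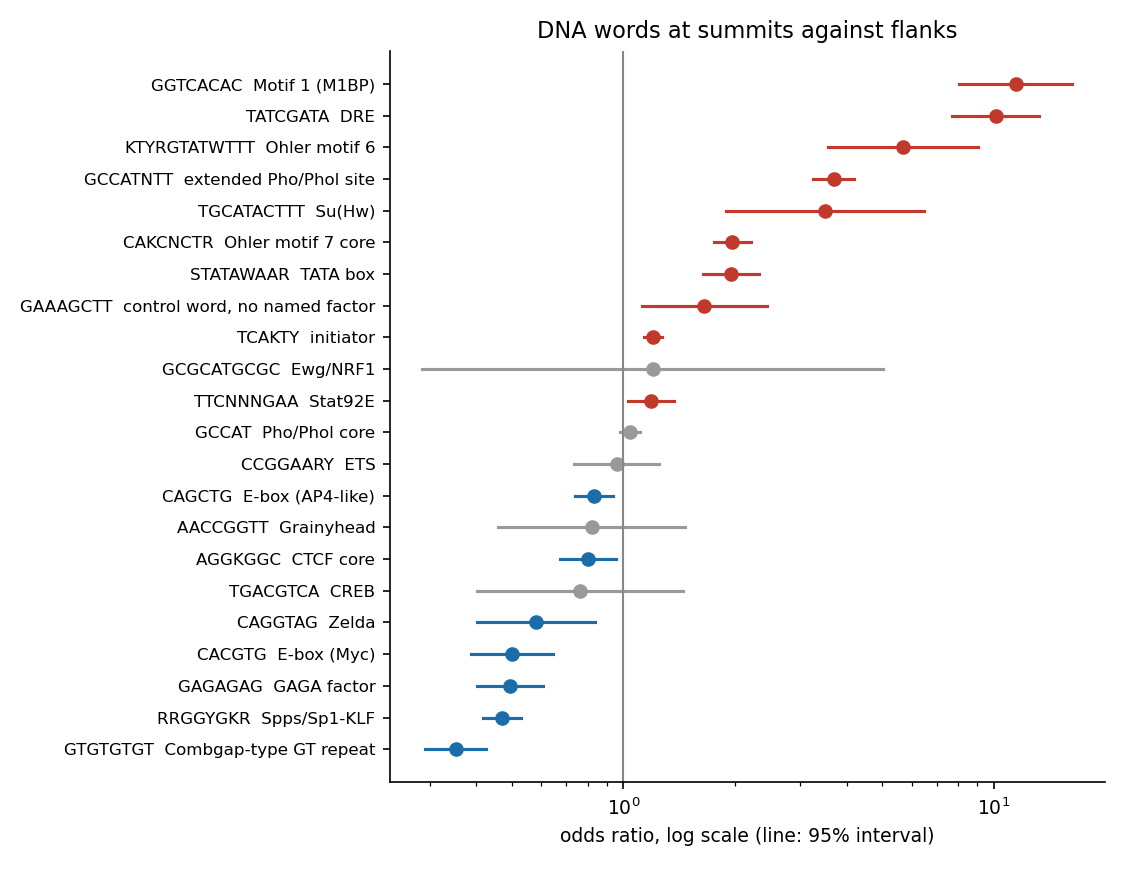
Odds ratio (log scale) of each of 22 DNA words within 50 bp of the summits against windows 500 bp away, with 95% intervals as lines. Red words were more frequent at summits and blue words less frequent after adjustment, and grey words were neither; Motif 1 (11.5) and the DNA replication-related element (10.1) have the highest ratios.

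Before sites at start codons were left out, core words near occupied starts read GCCAT on the sense strand more often than those near other starts. Within 100 bp of the start, 1235 of 2259 sites (54.7%) read this way at the 5688 protein-coding genes with a peak, against 1694 of 3310 (51.2%) at the 8257 genes without (odds ratio 1.15, 95% interval 1.03 to 1.28; Fisher's exact test, two-sided p = 0.0110). The replicates gave 55.1% ± 0.503 (SD, n = 3) at occupied starts. For GCCATNTT the shares were 47.1% of 380 sites and 34.8% of 305 (odds ratio 1.67). Occupied starts did not hold more GCCAT sites, with 39.7 per 100 starts against 40.1, while GCCATNTT was at 6.68 per 100 against 3.69. For occupied genes the start nearest a summit was used, and for other genes the most upstream annotated start. The groups thus differ also in how the start was picked, which can itself raise a word found at summits. Without sites at annotated start codons, which the reverse reading ATGGC can hold, the call ended for both words: the odds ratio was 1.11 (95% interval 0.989 to 1.24) for GCCAT and 1.37 (95% interval 0.967 to 1.94) for GCCATNTT. A site within 100 bp of both starts of a divergent gene pair counts for each gene, in opposite readings. This pulls a share towards an even split. Genes with a divergent neighbour were occupied more often (69.1% against 24.7% of others), and the orientation was not tested without such pairs.

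Peaks of tagged Phol lay at the promoters of a large minority of genes. Each replicate list was called with a control alignment, which is not analysed here. Promoter peaks that would arise without Phol therefore cannot be told apart, here or in the gene lists below. Of 13945 protein-coding genes, 5688 (40.8%) had a summit within 500 bp of a start, and the replicates gave 5646 ± 436 genes (SD, n = 3), with 4769 genes in all 3. The strongest 5132 peaks alone reached 3593 genes. Of the 18 gene lists fixed beforehand, 11 were occupied more often than other genes, 4 less often and 3 neither (Fisher's exact test, adjusted over the 18 lists). Random lists matched on the number of starts and on divergent neighbours moved several odds ratios towards 1 by over 1.5 times, though each of these calls held. For cytosolic ribosomal proteins the ratio fell from 19.6 to 10.5, for mitochondrial ribosomal proteins from 3.87 to 2.04, for the proteasome from 14.1 to 7.99, for aminoacyl-tRNA synthetases from 4.92 to 2.87, for the mitosis and condensin list from 13.5 to 8.99 and for the trithorax group from 21.9 to 10.6, and for the spliceosome it was 8.22. For chemoreceptors it rose from 0.0120 to 0.0227, for cuticle proteins from 0.0265 to 0.0565 and for the chorion and yolk list from 0.145 to 0.223. The window also moved the ratios of chemoreceptors and cuticle proteins, to 0.0522 and 0.0943 with 1 kb and to 0.00880 and 0.00960 with 200 bp.

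Genes for the basic machinery of the cell were occupied in most cases. The genes of cytosolic ribosomal proteins led, with 80 of 86 occupied (93.0%; 94.6% ± 0.671, SD, n = 3; adjusted p = 9.9e-24, Fisher's exact test). RpS30 (rank 14), RpL14 (rank 19) and RpS25 (rank 45) had the strongest peaks, and 24 of the list were among the strongest 1000 peaks. The 6 without a peak were RpL10Aa, RpL40, RpS10a, RpS15Ab, RpS19b and RpS9. Of the subunits of the proteasome, which degrades tagged proteins, 29 of 32 were occupied (90.6%), but 0 of them were among the strongest 1000 peaks. The best were Rpn3 (rank 1277), Rpn5 (rank 1664) and Rpn6 (rank 2189). The spliceosome list had 26 of 28 (92.9%), led by SmD3 (rank 12), Prp3 (rank 69) and Prp8 (rank 191). The odds ratio of the proteasome list, 14.1, was 8.11 without replicate 2, 8.68 with a single start per gene and 3.72 in the strongest 5132 peaks. That of the spliceosome list was also lower than in the whole list without replicate 1 (11.1), without replicate 2 (8.61) and in the strongest 5132 peaks (8.69).

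Of the aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, 27 of 35 were occupied, led by SerRS (rank 448) and IleRS (rank 506). The 8 without a peak all carry the suffix of the mitochondrial enzymes (AlaRS-m, AspRS-m, GluRS-m, IleRS-m, MetRS-m, PheRS-m, TyrRS-m and ValRS-m), a suffix that the occupied ArgRS-m, AsnRS-m, CysRS-m, LeuRS-m, ProRS-m, SerRS-m and TrpRS-m share; these enzymes were not tested as a class. The odds ratio of the synthetase list was 4.92, and fell to 2.46 without replicate 1, 3.16 without replicate 2 and 2.17 in the strongest 5132 peaks. The mitochondrial ribosomal protein list had 53 of 73 (72.6%; 74.9% ± 5.54, SD, n = 3), with mRpS16 (rank 2), mRpL41 (rank 21) and mRpS10 (rank 25) the strongest. Oxidative phosphorylation had 54 of 86 (62.8%; 62.0% ± 9.68, SD, n = 3), with COX5A (rank 255) and SdhC (rank 358) the strongest. Its odds ratio of 2.46 fell to 1.55 without replicate 2, where the call was lost (adjusted p = 0.0682, Fisher's exact test) and to 1.47 in the strongest 5132 peaks, where it was lost too (adjusted p = 0.128, Fisher's exact test).

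Genes of the cell cycle were also occupied more often. The DNA replication list had 29 of 38 (76.3%; 75.4% ± 13.5, SD, n = 3), led by RnrS, a subunit of ribonucleotide reductase (rank 92), the cyclin gene CycE (rank 379) and geminin (rank 400). The mitosis and condensin list had 37 of 41 (90.2%), led by tum (rank 415), fzy (rank 595) and the cohesin loader gene Nipped-B (rank 652). The unoccupied members included stg and twe, the Cdc25-type phosphatases that trigger mitosis and meiosis. The odds ratio of the DNA replication list, 4.70, was 2.83 without replicate 1 and 2.10 in the strongest 5132 peaks, and that of the mitosis list, 13.5, was 7.63 without replicate 1, 7.73 without replicate 2 and 6.25 in the strongest 5132 peaks.

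Chromatin regulators of the Polycomb and trithorax groups were among the most occupied lists. Of 27 Polycomb group genes, 23 were occupied (85.2%; 80.2% ± 9.32, SD, n = 3; odds ratio 8.38, Fisher's exact test, adjusted p = 6.6e-06), led by cg (rank 2), Jarid2 (rank 8) and Scm (rank 27). The odds ratio was 3.69 without replicate 1, 3.74 without replicate 2 and 4.21 in the strongest 5132 peaks. The peak of ph-p had rank 35, E(z), the histone methyltransferase, rank 334, Su(z)12 rank 394 and Pcl rank 434, while Pc had rank 5416. The 4 members without a peak within 500 bp were Psc, Sce, Su(z)2 and escl. The summit nearest a start of Psc had rank 133 and lay 4210 bp away (2R, 12985204), between Psc and Su(z)2. Of 32 trithorax group genes, which keep developmental genes active, 30 were occupied (93.8%; 89.6% ± 3.61, SD, n = 3), led by osa (rank 11), brm (rank 32) and kis (rank 104). The exceptions were kto and tna. The odds ratio of this list, 21.9, was 9.97, 10.1 and 8.30 without replicates 1, 2 and 3, and lowest with a window of 200 bp (6.47).

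**Figure D3:**
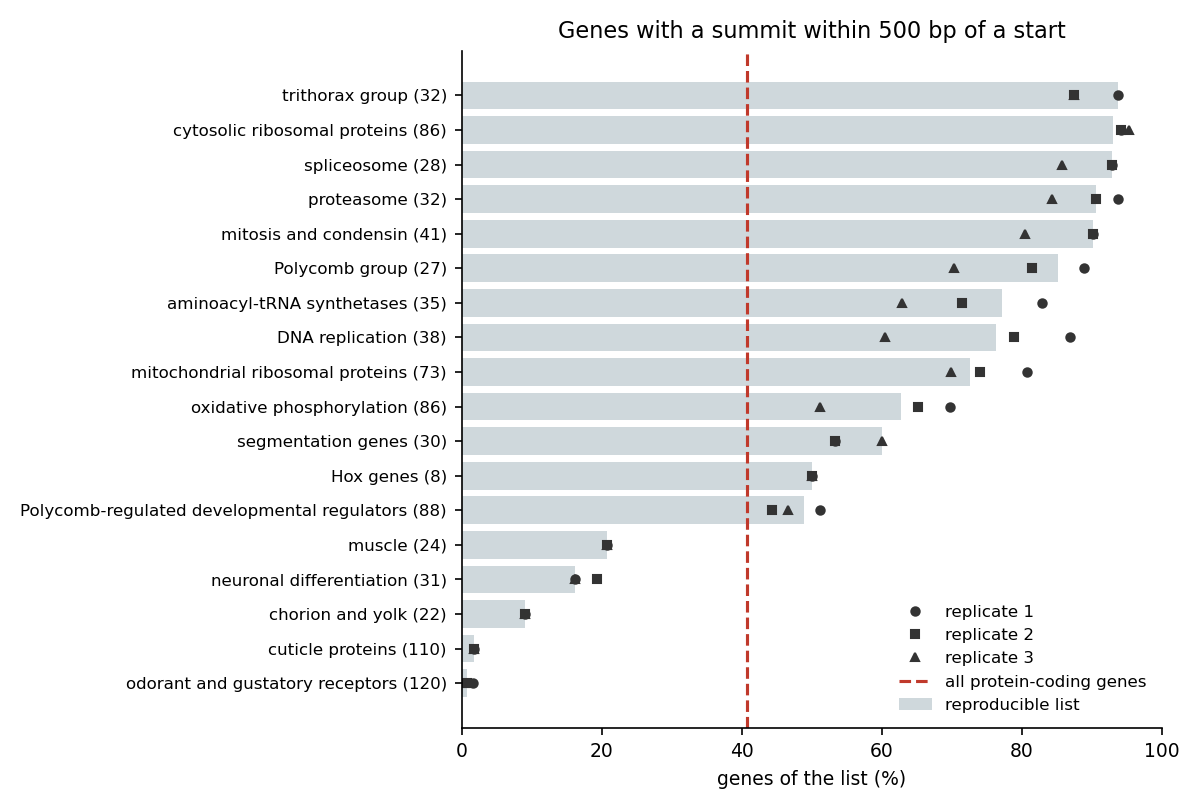
Percent of the genes of each list, with the number of genes in brackets, that had a summit within 500 bp of a start: bars are the reproducible list, points the strongest 10264 peaks of each of the 3 replicates, and the dashed line all protein-coding genes (40.8%). Cytosolic ribosomal proteins (93.0%) and the trithorax group (93.8%) lie at the top, odorant and gustatory receptors (0.833%) at the bottom.

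In these whole embryos of 0 to 16 hours, genes of differentiated tissues mostly had no peak at their promoters. Whether Phol is found there in the tissues that use these genes was not measured. Only Gr63a, a carbon dioxide receptor (rank 5266), was occupied of 120 odorant and gustatory receptor genes (0.833%; 1.11% ± 0.481, SD, n = 3; Fisher's exact test, adjusted p = 8.1e-25). Of 110 cuticle protein genes 2 were occupied, Lcp9 (rank 6247) and Cpr65Ea (rank 8593). The neuronal differentiation list had 5 of 31 (16.1%, Fisher's exact test, adjusted p = 0.00676), led by elav, an RNA-binding protein of all neurons (rank 260), then comt (rank 2541) and Csp (rank 5830). The chorion and yolk list had 2 of 22, Cp190 (rank 22) and Cp110 (rank 9626). Both were taken in by their symbols and encode an insulator and centrosome protein and a centriole protein, not parts of the eggshell. Without them, 0 of 20 were occupied (Fisher's exact test, adjusted p = 5.2e-05). With them, the odds ratio of 0.145 was 0.0885 without replicate 2 and 0.0727 without replicate 3. The muscle list had 5 of 24 (20.8%), which did not pass the test (Fisher's exact test, adjusted p = 0.0672), led by Msp300 (rank 895), Tm1 (rank 1134) and Act87E (rank 1407). It did with a window of 200 bp (adjusted p = 0.0192, Fisher's exact test), with a single start per gene (adjusted p = 0.0408, Fisher's exact test) and against matched random lists (permutation test, adjusted p = 0.00742).

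Developmental regulators under Polycomb control gave a mixed picture. Of 88 such genes, 43 were occupied at a promoter (48.9%; 47.3% ± 3.47, SD, n = 3), which did not pass the test against other genes (odds ratio 1.39, Fisher's exact test, adjusted p = 0.136). Against matched random lists, which had 29.4% occupied, the list was occupied more often (permutation test, adjusted p = 6.0e-04). The strongest were Poxm (rank 339), abd-A (rank 361) and Dfd (rank 425). The segmentation list, part of whose genes are also in the list above, had 18 of 30 (60.0%, Fisher's exact test, adjusted p = 0.0479), led by pan (rank 430), cad (rank 478) and ptc (rank 607). Unoccupied were Kr, ftz, gsb, hb, hh, hry, kni, knrl, odd, prd, run and slp2. The call was lost with any single replicate left out (Fisher's exact test, adjusted p from 0.0644 to 0.297), in the strongest 5132 peaks (0.119), with windows of 200 bp (0.593) and 1 kb (0.158), and with a single start per gene (0.148). Against matched random lists, which had 27.7% occupied, it held (permutation test, adjusted p = 4.0e-04).

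Of the 8 Hox genes, which give body segments their identity, 4 had a promoter peak, a share that did not pass the test against other genes (odds ratio 1.45, Fisher's exact test, adjusted p = 0.723). The peaks of abd-A (3R, 16830025 to 16830402) and Dfd (3R, 6791343 to 6791872) were in the strongest 1.16% ± 0.253 and 1.48% ± 0.465 of the replicate lists (SD, n = 3). Those of Antp (rank 6071) and Abd-B (rank 7122) were weaker. None lay within 500 bp of a start of lab, pb, Scr or Ubx, but Ubx held 7 summits within the gene, lab 4 and pb 3, while Scr held 0. The promoter of en had a peak of rank 4020, and its neighbour inv had none, with a summit of rank 1152 lying 4822 bp from its start. From 5 kb upstream to the gene end, 72 of the 88 Polycomb-regulated genes (81.8%) held a summit, against 74.6% (95% range 65.9 to 83.0) of 10000 random lists matched on gene length, which did not pass the test (permutation test, two-sided p = 0.0818).

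**Figure D4:**
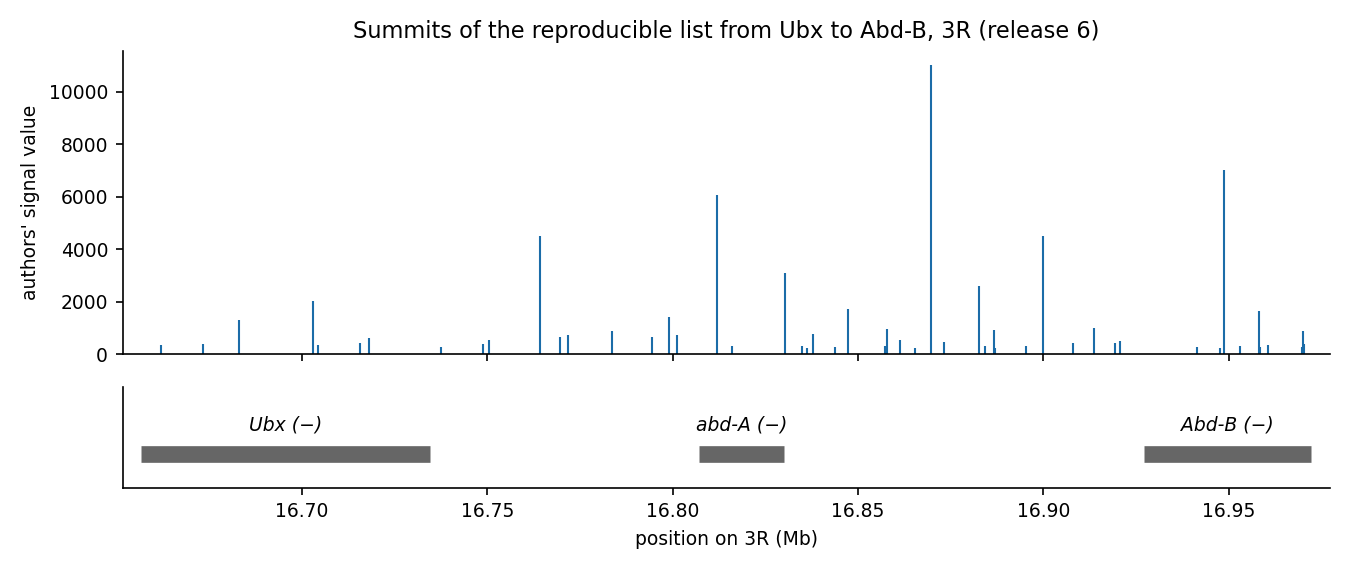
Summits of the reproducible list from Ubx to Abd-B on 3R (release 6 position in Mb), with the authors' signal value as the height of each line and the 3 Hox genes, all on the minus strand, as bars. The highest line, of rank 17, lies between abd-A and Abd-B.

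Genes with a divergent neighbour were occupied far more often than others. Of 5052 protein-coding genes whose start lay within 1 kb of a start on the other strand pointing away, 3490 (69.1%) were occupied, against 2198 of 8893 others (24.7%), an odds ratio of 6.81 (95% interval 6.30 to 7.35) by Fisher's exact test. The difference was 44.1 percentage points ± 2.51 (SD, n = 3). The pair cg and mRpS16 is an example, with a single summit within 500 bp of both genes. Counted by promoter region, so that such a summit counts once, 72.5% of 2453 divergent regions and 22.5% of 10673 others were occupied.

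On the X chromosome 963 of 2196 genes (43.9%) were occupied, against 4692 of 11669 (40.2%) on chromosomes 2 and 3 (odds ratio 1.16, 95% interval 1.06 to 1.27; Fisher's exact test, two-sided p = 0.00152). X was higher in 3 of 3 replicates, by 3.22 percentage points ± 1.57 (SD, n = 3). The embryos were of mixed sex, and the number of X copies was not accounted for. The direction turned in the strongest 5132 peaks (odds ratio 0.885, Fisher's exact test, two-sided p = 0.0254), and the call was lost without replicate 1 (p = 0.0756, Fisher's exact test), without replicate 2 (p = 0.435, Fisher's exact test) and with a window of 200 bp. Chromosome 4, which carries pho, had 33 of 80 genes occupied (41.3%), which did not pass the test against chromosomes 2 and 3 (odds ratio 1.04, 95% interval 0.668 to 1.63; Fisher's exact test, two-sided p = 0.909).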

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

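These results were looked for after the main results were seen, in the 19735 peaks of the pooled list on the 6 arms that did not reach the reproducible list and that no comparison above uses. They were flagged because a signal above the background appeared in data outside the main measurement. Of these weaker peaks, 24.7% had their summit within 500 bp of a start, against 13.6% at random (permutation test, 100 placements, two-sided p = 0.0198, the smallest they can give). GCCATNTT stood within 50 bp of the summit in 4.39%, against 1.74% of flanks (odds ratio 2.60, 95% interval 2.35 to 2.88). The DNA replication-related element stood there in 0.790%, against 0.241% (odds ratio 3.30, 95% interval 2.56 to 4.26). A summit lay within 250 bp in all 3 full replicate lists for 48.7% of them, against 5.73% at random, but the pooled list was called on the reads of these replicates, so a high share follows in part from how it was made.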

How the results depend on the processing

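Over the results that answer a comparison, 79 of 96 alternatives that change the peaks, windows or test kept the direction and side of the threshold, or a count within 1.5 times. The strongest 10264 peaks of the pooled list and the inclusion of Y and unplaced sequences gave identical peaks and say nothing about stability. Among these, overlap, promoter share and divergent promoters kept direction and side under every alternative run. Orientation did under the other windows, words and peak lists, but its call ended without start-codon sites (odds ratio 1.11 for GCCAT, 1.37 for GCCATNTT), a test counted apart. The odds ratio of GCCAT against flanks depended on the setting: 0.994 to 1.04 with a replicate left out, 1.20 in the strongest 5132 peaks, 1.25 within 25 bp, 0.870 within 100 bp, and 1.37 against peak-free promoters. The mean over other orderings of its letters was 0.712. With GCCATNTT it was 3.69. Chosen after seeing the data, GCCATNTT gave 4.47 at promoter peaks and 3.05 away from them, and GCCAT against random positions gave 0.987. By peak strength, GCCAT gave 1.01 away from promoters. The X odds ratio was 1.04 to 1.13 with a replicate left out, 1.09 with a window of 200 bp and 0.885 in the strongest 5132 peaks. These peaks reached 3593 genes, since the list is shorter. The share of Polycomb-regulated genes with a summit from 5 kb upstream to the gene end, 81.8% against 74.6% at random (permutation p = 0.0818), was 75.0 to 76.1% with a replicate left out (permutation p from 0.266 to 0.635), 59.1% against 56.5% in the strongest 5132 peaks (permutation p = 0.699), 46.6% against 46.6% without the upstream part (permutation p = 0.899) and 97.7% against 92.9% with 20 kb on either side (permutation p = 0.0846). Only summits away from starts, chosen afterwards, passed the test (63.6% against 44.1%). For single gene lists, 128 of 145 alternatives kept the main call, 9 lost it, 4 gained it and 4 turned direction. Hox genes had odds ratios of 0.960 in the strongest 5132 peaks, 0.716 with 200 bp and 0.533 with a single start per gene, and Polycomb-regulated genes 0.804 with 200 bp. No paired analysis was possible because the series has a single group. Except for the shorter list, the cause was not tested. With 8 Hox genes and unknown read depth, small differences cannot be resolved.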

Other observations

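Of the tests here, those comparing a word with each other ordering of its letters (for GCCAT, only the mean over orderings was planned), on divergent promoters by region, on words by peak location and on Polycomb-regulated genes away from starts were chosen after the related result was seen, as were the regions described next. The bithorax complex, from Ubx to Abd-B (3R, 16656623 to 16972236), held 51 summits, 46 of them more than 500 bp from a start, a density of 16.2 per 100 kb against 7.67 over the 6 arms. Of these, 9 were among the strongest 1000 peaks. Besides the peak of rank 17, they included a summit in Abd-B of rank 53 (3R, 16948767) and a summit in abd-A of rank 73 (3R, 16811914) with GCCATNTT. The Antennapedia complex, from lab to Antp (3R, 6661427 to 6999228), held 39 summits (11.5 per 100 kb), 4 of them among the strongest 1000. The span of the genes inv and en (2R, 11474465 to 11528210) held 3 (5.58 per 100 kb), 2 of them inside inv and the best of rank 5041. The summits at the en promoter (11528369, rank 4020) and upstream of inv (11469643, rank 1152) lie just outside that span, so its density depends on where the edges are set. From Psc to Su(z)2 there were 4 (9.54 per 100 kb). No test of these densities was run. The strongest summits away from starts outside the bithorax complex, after that of mts, were nearest to CG4004 (rank 31), cbt (rank 33), CG11050 (rank 41), lwr (rank 47) and Trl (rank 51). Counting only summits away from starts, 63.6% of the Polycomb-regulated genes held one, against 44.1% of length-matched random lists (permutation test, two-sided p = 2.0e-04, the smallest they can give), while the planned test on all summits did not pass (permutation p = 0.0818). The lists were not matched on how much sequence near each gene lies away from the starts of any gene. The difference therefore cannot be assigned to Polycomb regulation.

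Promoter peaks and other peaks differed in their DNA words. The DNA replication-related element was at 5.93% of 5080 promoter peaks and 0.347% of 5184 others, Motif 1 at 3.74% and 0.347%, and Ohler motif 7 at 10.1% and 1.95%. GCCATNTT was at 7.30% and 5.98% (odds ratio 1.24, 95% interval 1.06 to 1.45). The Su(Hw) site went the other way, at 0.118% and 0.424% (odds ratio 0.277, 95% interval 0.112 to 0.685).

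The summits were AT-rich, with 33.5% G and C. The parts of genes they lie in do not account for this, since random positions of the same classes had 41.4%, and promoter summits had 35.6% against 40.9% at matched positions of starts without a peak. Weak peaks do not account for it either, because the strongest 1026 peaks differed from the weakest 1027 by -1.99 points, and pooled peaks below the reproducible list had 40.9%. Composition alone did not give the excess of GCCATNTT, whose odds ratio was reached by 0 of 100 other orderings (0% of them, the highest at 1.82), but whether it hides an excess of GCCAT is open, since GCCAT was above 91.5% of the other orderings, whose median was 0.673. A bias of fragmentation or sequencing towards AT-rich DNA was not tested, as the reads and the control are not analysed here, and no biological explanation was tested.

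Counting a summit for both genes of a pair does not explain the occupancy of divergent promoters, since the odds ratio by promoter region was 9.07 (72.5% of 2453 divergent regions and 22.5% of 10673 others). The greater width of divergent regions alone does not explain it either: their occupied share was 3.22 times that of other regions, and 100 random placements gave at most 1.64 times. These placements ignore that summits gather at starts. A divergent region holds starts on both strands, and the effect of the number of starts in a region was not tested. Gene expression, which may differ between these groups of genes, is not analysed here and stays open.

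The higher share of sense GCCATNTT at occupied starts (47.1%) than at other starts (34.8%), which is below an even split at both, may come in part from start codons, since ATGGC, the reverse reading of GCCAT, is how a coding sequence can begin. At occupied starts 33.8% of the reverse sites were annotated start codons, and at other starts 45.7%. Without them the odds ratio fell from 1.67 (95% interval 1.23 to 2.28) to 1.37 (95% interval 0.967 to 1.94), and for GCCAT from 1.15 to 1.11 (95% interval 0.989 to 1.24), so the call ended through a smaller ratio and a wider interval. Sites counted for both genes of a close divergent pair, in opposite readings, were not left out and pull a share towards an even split. A remaining orientation of the site is not excluded.

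A hypothesis that extra copies of the phol region carried by the transgene could raise peaks around phol was tested on the pooled peaks within 20 kb of phol, which do not include the strong Jarid2 peak 20742 bp from its start. Their median signal was above that of 78.8% of 12132 genes, between the bounds set beforehand, and their number, 26, was above that at 92.4% of genes. This leaves the hypothesis open, and the test says nothing about the Jarid2 peak. The hypothesis that strong summits away from starts lie at Polycomb-regulated genes more often than weak ones was not borne out or excluded, with 60 of the strongest 1296 and 68 of the weakest 1296 nearest to such a gene (odds ratio 0.877, 95% interval 0.614 to 1.25). The hypothesis that the DNA replication-related element and GCCATNTT mark different promoter peaks was not borne out: 21 peaks held both, with GCCATNTT at 6.98% of promoter peaks with the element and 7.32% of those without (odds ratio 0.949, Fisher's exact test, two-sided p = 0.909). The 95% interval included 1, the bound set beforehand against the hypothesis, but that bound was too loose, since the interval starts at 0.601 and a moderate shortage of joint peaks is not excluded.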
